A study of Homo sapiens with 6 samples.

How the data were processed

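MDA-MB-231 cells were grown for 48 h without the drug or with DCC-2036 at 3.75 μM in 3 experiments described as independent, per the labels, and total RNA from each culture was turned into double-stranded cDNA with an oligo dT primer, labelled with Cy3 and hybridized to a one-colour NimbleGen expression array. The deposited table holds one intensity per transcript record and array, 45033 records on 6 arrays. RMA was used to make these intensity values, per the submitters' processing notes, which give no version. The intensities ran from 8.03 to 65365 and were on a linear scale, and the columns had close medians, so they were used as deposited with no further normalization. The method of background correction, the number of probes per record, the scanner and the array's genome build are not given in the sources used here, so no genome coordinates are printed. The table has no background or detection column, so a dim record could not be called absent, and it names no slide or scan date, so a batch could not be tested. Signals of near-identical gene copies could not be told apart.

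Of the 45033 records, 18188 were named by the platform's annotation table, each with a single symbol and 0 with several, and 678 more by their RefSeq accession in a RefSeq gene table of assembly GRCh38.p14, used for names only. The other 26167 records had no name here and were tested only at the level of records. The named records stood for 17185 genes, 1349 of them with more than 1 record, and each gene was represented by the record with the highest mean over the 6 arrays. In 14 of the 564 such genes with a record past the threshold, records passed in both directions.

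Values were put on the log2 scale after adding 1. Both groups of 3 arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all 17185 genes and a threshold of 0.05, and a count with a change of at least 2-fold was taken beside it. Standard errors are those of limma. Folds are 2 to the power of the log2 change. An exact permutation test of 3 against 3 arrays cannot give a two-sided p below 0.1, so no such test is given for single genes. The 29 gene lists were tested with camera (preset correlation 0.01, adjusted over the 29 lists, threshold 0.05) and with fry. The count of members past the threshold is given over all genes and adjusted over the list alone. Genes named are the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap (symbols that are only clone or locus numbers were skipped), up to 4 members with the smallest p from each list, and AXL, MET, ABL1, TEK, SRC, CDKN1A, CCND1, MKI67 and MYC. Some genes that this rule picks are not reported here. The test, the lists, this rule and the alternatives were chosen before the data were examined, except that the alternatives were extended afterwards to single records, to counts of list members, to genes named beyond the rule and to gene groups added later. Members of a list named beyond this rule, to spell out a small count, were chosen after their values were seen.

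The procedure was tested on simulated data for this comparison, with 17185 genes, 3 arrays per group and 200 genes changed, in 20 runs. It recovered 0.149% of genes changed by a log2 of 0.5, 18.7% of those changed by 1 and 62.0% of those changed by 2, with 5.25% false genes among the calls, and it called a list shifted by 1 in 100% of runs and 0 other lists per run. Simulated genes varied independently of each other, whereas the correlation estimated in the data for the NF-kB list was 0.37. The 0 other lists therefore give no rate of false list calls for these data. Recovery of single genes was measured with far fewer changed genes than the 5003 called in the data. The alternatives tried were quantile normalization again, median centring, 16 in place of 1 added before the log, leaving out the dimmest 25% or the dimmer part (below the median) of records, eBayes with trend and robust settings, a plain t-test, the mean of a gene's records or its second brightest record, array weights, a replicate block, other thresholds, a correlation estimated per list, lists tested among brighter genes only, and each array left out in turn. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 made the tables of names and the figures.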

Results

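The data were 6 one-colour expression arrays of MDA-MB-231, an established human triple-negative breast cancer cell line, 3 from control cultures (0 μM drug) and 3 from cultures given DCC-2036 at 3.75 μM and sampled after 48 h. DCC-2036, also called rebastinib, is an inhibitor of the kinase ABL1 that also acts on TEK, the TRK receptors and SRC-family kinases. Each array gave an intensity for 45033 transcript records, of which 18866 had a gene name and stood for 17185 genes. Median intensities were 266, 274 and 265 in control replicates 1, 2 and 3 and 269, 273 and 267 in DCC-2036 replicates 1, 2 and 3. Pearson correlations of the log2 values, taken across the 17185 genes, lay between 0.964 and 0.978 within a group and between 0.929 and 0.937 across groups. The first principal component, with 55.6% of the variance, separated the groups, and the second held 15.0%. The number of arrays, 3 per group, limits the precision of every value below.

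The comparison of treated with control cells asked which transcripts differ after 48 h with the drug. Treated cells had less mRNA for DNA replication and mitosis, with 36 of 39 replication genes and 42 of 42 mitosis genes lower. Of 31 NF-kB targets and inflammatory cytokines, 19 fell and 11 did not pass, with IL6, a secreted cytokine, 29.9-fold lower and IL1A, an alarmin cytokine, down by a log2 change of -4.65. Among targets of the Hippo pathway co-activators YAP and TAZ, 16 of 22 fell, and among genes of ERK signalling output 16 of 32 did. Genes of hypoxia and glycolysis and of oxidative phosphorylation rose in smaller numbers, 13 of 38 and 12 of 40 (the latter 7 without control replicate 1, control replicate 2 or DCC-2036 replicate 3 and 6 without DCC-2036 replicate 2). The largest rises included TSC22D3, a glucocorticoid- and FOXO-responsive transcription regulator, at 13.2-fold, and CSF1R, the receptor of colony-stimulating factor 1, at 9.89-fold. In the limma test, 2257 of 17185 genes were higher and 2746 lower with DCC-2036 at an adjusted p under 0.05, and 1056 and 1460 of them differed by at least 2-fold. The lower genes made up 54.9% of the changed ones. In 46.5% of genes all 3 treated values lay on one side of all 3 control values, where chance gives 10%. Without control replicate 1 the counts were 1422 higher and 1725 lower, and without DCC-2036 replicate 2 there were 1461 higher.

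**Figure D1:**
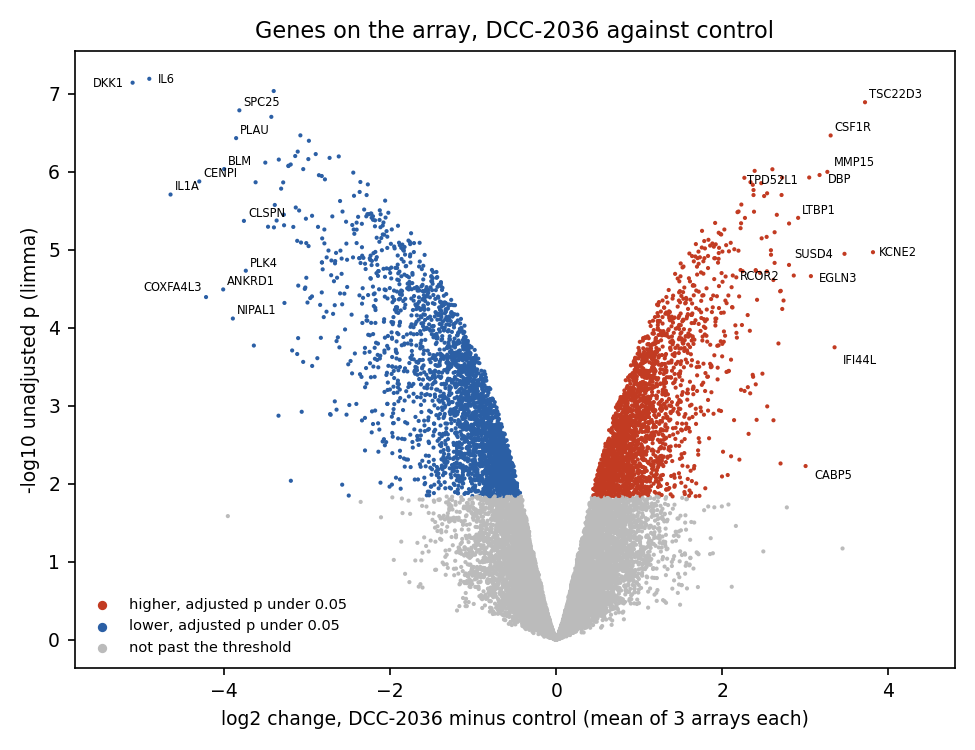
Log2 change of each of the 17185 genes (DCC-2036 minus control, means of 3 arrays each) against -log10 of the unadjusted limma p. Red points are the 2257 higher genes and blue points the 2746 lower genes at an adjusted p under 0.05, grey points did not pass, and the 12 largest named rises and the 12 largest named falls carry their symbols, with DKK1 at -5.10 and KCNE2 at 3.82 farthest out.

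Intensities are given as mean ± SD of 3 arrays and log2 changes with their standard error. DKK1, a secreted inhibitor of Wnt signalling, fell the most: its intensity was 23146 ± 1394 in the control arrays and 681 ± 130.5 with DCC-2036, a log2 change of -5.10 ± 0.19 (limma adjusted p = 0.000531). IL6 followed, with 20120.2 ± 952 in the control arrays and 679 ± 119.9 with DCC-2036, a log2 change of -4.90 ± 0.18 (limma adjusted p = 0.000531). IL1A had 5718 ± 739.9 in the control arrays and 237 ± 93.7 with DCC-2036 (-4.65 ± 0.29). PLAU, the urokinase protease that activates plasminogen, fell 14.5-fold, with 12654 ± 884 in the control arrays and 882 ± 156 with DCC-2036. ANKRD1, a muscle ankyrin-repeat protein and YAP target, fell 16.1-fold (-4.01 ± 0.39), and COXFA4L3, a small mitochondrial protein, 18.6-fold (-4.22 ± 0.42). The other large falls were in genes of chromosomes and division or in transport: CENPI, a centromere protein (-4.30 ± 0.25), BLM, the Bloom syndrome helicase (358 ± 32.2 in the control arrays and 21.9 ± 5.38 with DCC-2036), NIPAL1, a magnesium transporter (-3.89 ± 0.43), SPC25, a kinetochore component (-3.82 ± 0.16), CLSPN, a replication checkpoint adaptor (-3.76 ± 0.26), and PLK4, the kinase of centriole duplication (-3.74 ± 0.33). In CENPI, BLM, NIPAL1, SPC25 and PLK4 the treated mean lay in the dimmest 25% of records (intensity under 66.3), and with 16 in place of 1 added before the log CENPI changed by -3.52, BLM by -3.31 and SPC25 by -3.20. COXFA4L3 had more than 1 record, and the second changed by -2.41 (mean of records -3.31).

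Among the rises, KCNE2, a potassium channel subunit, had the largest log2 change, 3.82 ± 0.31, from a dim control mean, with 51.5 ± 21.9 in the control arrays and 702 ± 96.6 with DCC-2036. TSC22D3 was brighter, with 638 ± 24.9 in the control arrays and 8448 ± 950.4 with DCC-2036 (3.72 ± 0.15, limma adjusted p = 0.000555). CSF1R reached 9.89-fold, with 108 ± 13.0 in the control arrays and 1077 ± 71.1 with DCC-2036. MMP15, a membrane-bound matrix metalloproteinase (3.27 ± 0.18), DBP, a circadian PAR bZIP transcription factor (3.17 ± 0.18), EGLN3, an oxygen-sensing prolyl hydroxylase (3.07 ± 0.28), TPD52L1, a tumour protein D52 family member (3.05 ± 0.17; 4.01 with its second record), and LTBP1, a latent TGF-beta binding protein (2.91 ± 0.20), rose between 7.53-fold and 9.62-fold. IFI44L, an interferon-induced gene (3.35 ± 0.43), and RCOR2, a corepressor (2.86 ± 0.26), started from dim control signals, as did SUSD4, a complement regulator (3.47 ± 0.28), whose second record gave 0.12 and did not pass (mean of records 1.80). CABP5, a calcium-binding protein (3.00 ± 0.74; 3.84 without control replicate 1), lost its call without control replicate 2 (2.78), DCC-2036 replicate 2 (2.98), control replicate 3 (2.39) or DCC-2036 replicate 3 (2.74).

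**Figure D2:**
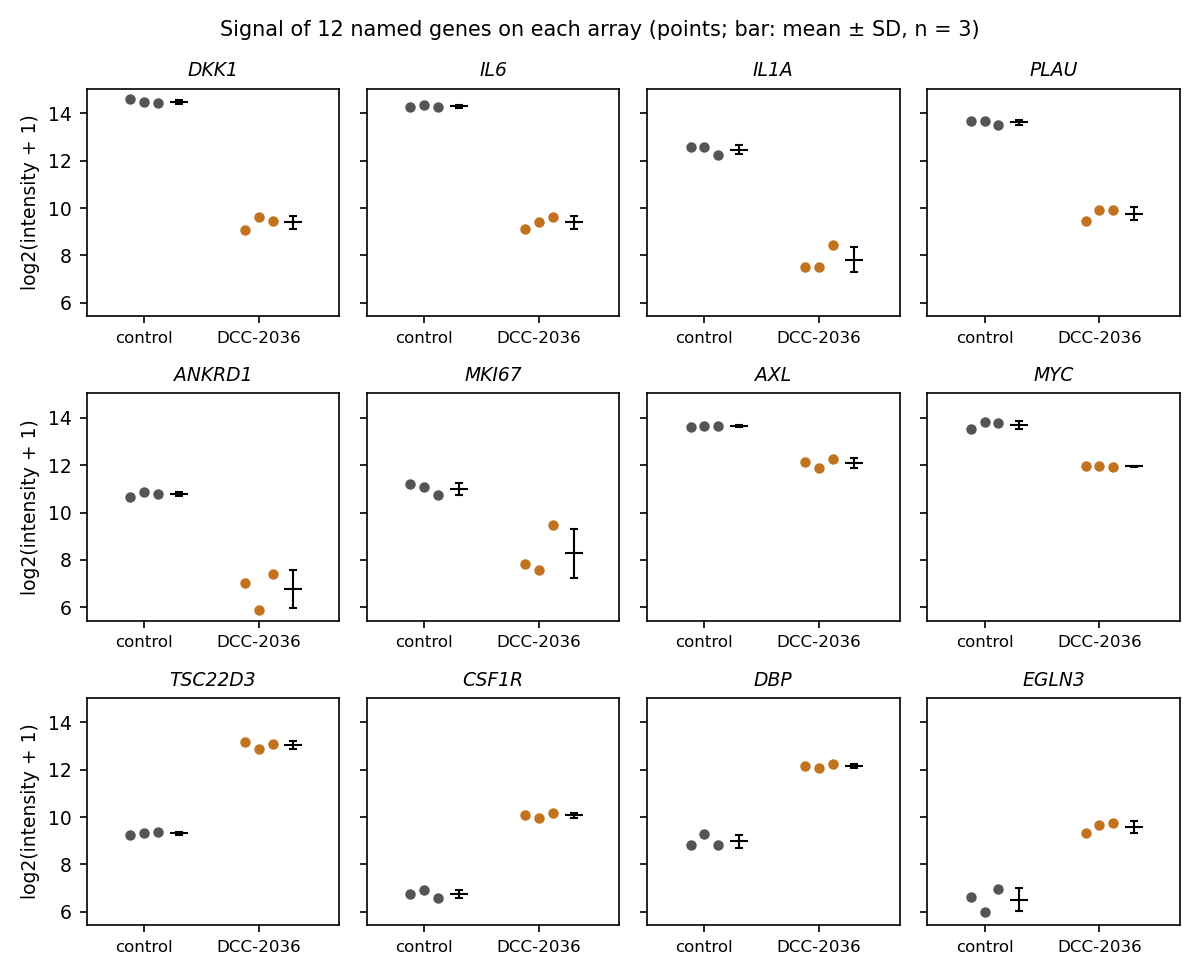
Log2 of intensity plus 1 of 12 genes on each array; points are single arrays in control (grey) and DCC-2036 (orange), and bars give the mean ± SD of 3 arrays. DKK1, IL6, IL1A, PLAU, ANKRD1, MKI67, AXL and MYC lay lower with DCC-2036 on every array, and TSC22D3, CSF1R, DBP and EGLN3 higher.

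Cell division genes were lower as groups. Of 39 DNA replication and G1/S genes measured, 0 rose, 36 fell and 3 did not pass (adjusted over the list alone, 0 higher and 37 lower), and the median log2 change was -1.90. GINS4, a subunit of the replicative helicase, fell 8.46-fold (-3.08 ± 0.14), MCM10, a replication initiation factor, 9.18-fold (-3.20 ± 0.17; -2.42 with 16 added before the log), both with treated means in the dimmest 25% of records, DSCC1, a cohesion clamp loader, 4.33-fold and POLA1, the catalytic subunit of DNA polymerase alpha, 4.61-fold. The 3 members that did not pass were ORC1 (-0.99), POLD1 (0.09) and CDT1 (0.08), named after their values were seen. The camera adjusted p was 2.01e-18, and adjusted p = 0.178 with an estimated correlation. All 42 G2/M and mitosis genes fell, also when adjusted over the list alone (42 lower, 0 higher), with a median of -2.30. CENPF, a kinetochore protein, had 8261 ± 534 in the control arrays and 1342 ± 50.6 with DCC-2036, CDC25C, a phosphatase that activates CDK1, fell 8.84-fold and ASPM, a spindle pole protein, 11.3-fold. In the camera test the mitosis list had an adjusted p of 5.22e-25, and adjusted p = 0.178 with an estimated correlation. MKI67, the Ki-67 proliferation marker, was 2070.3 ± 338 in the control arrays and 371 ± 287 with DCC-2036 (-2.72 ± 0.50), and -3.31 without DCC-2036 replicate 3.

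Cyclin-dependent kinase inhibitors and p53-response genes moved both ways: of 30 measured, 5 rose, 9 fell and 16 did not pass (adjusted over the list alone, 5 higher and 11 lower; camera adjusted p = 0.345). PLK2, a p53-inducible kinase, fell 4.87-fold, BTG2, an antiproliferative gene, 3.72-fold and TNFRSF10B, a TRAIL death receptor, 2.76-fold, while CDKN1C, the inhibitor p57, rose 3.51-fold. The other higher members were FDXR, ZMAT3, BBC3 and CDKN1A. CDKN1A, the inhibitor p21, had 7331 ± 670.0 in the control arrays and 10159 ± 472 with DCC-2036 (0.47 ± 0.14, limma adjusted p = 0.0494), and its call was lost without each array in turn: control replicate 1 (0.46), DCC-2036 replicate 1 (0.51), control replicate 2 (0.54), DCC-2036 replicate 2 (0.46), control replicate 3 (0.42) and DCC-2036 replicate 3 (0.45). The count of 5 higher members was 3 without control replicate 1 or DCC-2036 replicate 3 and 2 without any of the other 4 arrays.

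Of 28 pro-apoptotic genes, 4 rose, 6 fell and 18 did not pass (adjusted over the list alone, 4 higher and 8 lower; camera adjusted p = 0.833); their median was 0.02 and their mean -0.07. BMF, a BH3-only protein, rose 4.15-fold with BAD (second record 0.28, not passing), BAK1 and BBC3 also higher, and PMAIP1, the BH3-only protein NOXA, fell 2.83-fold, as did DFFA, the inhibitor of a caspase-activated nuclease, by 2.75-fold. The 6 lower members dropped to 3 without control replicate 1, control replicate 2 or DCC-2036 replicate 2. Of 15 anti-apoptotic genes, 2 rose, 5 fell and 8 did not pass (adjusted over the list alone, 2 higher and 5 lower; camera adjusted p = 0.236). BIRC5, survivin, fell 2.95-fold and BIRC2, an inhibitor of apoptosis protein, 1.78-fold with BIRC3 and BCL2L1, and BAG3, a co-chaperone, and BCL2 (1.04; second record -0.71 and mean of records 0.17, neither passing) rose. BCL2L2 (-0.95) lost its call without control replicate 1 (-0.90). The 5 lower members dropped to 2 without control replicate 1 and 3 without control replicate 2 or control replicate 3, and the 2 higher members dropped to 1 without control replicate 1 or control replicate 2.

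Inflammatory genes formed another group that was lower. Of 31 NF-kB targets and inflammatory cytokines, 1 rose, 19 fell and 11 did not pass (adjusted over the list alone, 1 higher and 23 lower), with a median of -1.12. Beside IL6 and IL1A, IL1B, the secreted interleukin-1 beta, fell 4.19-fold, with 2130.0 ± 268 in the control arrays and 512 ± 107 with DCC-2036, and RELB, an NF-kB subunit, 3.05-fold. The higher member was BCL3, an atypical inhibitor of NF-kB (0.56), which did not pass without control replicate 1 (0.61), DCC-2036 replicate 1 (0.50), control replicate 2 (0.51), control replicate 3 (0.56) or DCC-2036 replicate 3 (0.50), each leaving 0 higher. CXCL8, the chemokine interleukin 8, singled out after its values were seen, was 17699.6 ± 4045 in the control arrays and 2479.8 ± 2067 with DCC-2036 (-3.96 ± 1.37) and did not pass (limma adjusted p = 0.0755), though it did without the dimmest 25% of records (0.0493) or the dimmer ones (0.0156). It was -2.24 and passed without DCC-2036 replicate 1, the dimmest of its arrays, and was -4.77 without DCC-2036 replicate 2 and -4.85 without DCC-2036 replicate 3. Against other genes the camera test gave an adjusted p of 1.30e-07, and adjusted p = 0.389 with an estimated correlation. Of 38 interferon-stimulated genes, 6 rose, 12 fell and 20 did not pass (adjusted over the list alone, 6 higher and 13 lower; camera adjusted p = 0.483). IFI44L and ISG15, a ubiquitin-like modifier (2.30-fold), rose, and HERC5, the ligase that attaches ISG15, fell 2.62-fold and IFIT2, an RNA-binding antiviral protein, 2.48-fold. The 6 higher members dropped to 3 without DCC-2036 replicate 2 and 2 without DCC-2036 replicate 3, and the 12 lower members dropped to 7 without control replicate 1, control replicate 2 or DCC-2036 replicate 2.

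Of 32 genes of ERK pathway output, 1 rose, 16 fell and 15 did not pass (adjusted over the list alone, 1 higher and 16 lower), with a median of -0.49. AREG, a ligand of the EGF receptor, fell 9.77-fold, with 1847 ± 208 in the control arrays and 189 ± 33.9 with DCC-2036, and the related ligands HBEGF and EREG fell 3.64-fold and 4.69-fold. MYC, a growth-promoting transcription factor, had 13461 ± 1449 in the control arrays and 3956 ± 64.8 with DCC-2036 (-1.76 ± 0.15, limma adjusted p = 0.00109), and CCND1, cyclin D1, fell 2.30-fold (-1.20 ± 0.17). The higher member was DUSP4, a nuclear MAP kinase phosphatase (0.65), with 0 higher without control replicate 1, control replicate 2 or DCC-2036 replicate 2. For this list camera gave an adjusted p of 0.000595, and adjusted p = 0.201 with an estimated correlation. Of 32 FOXO and PI3K-AKT output genes, 3 rose, 10 fell and 19 did not pass (adjusted over the list alone, 4 higher and 11 lower; camera adjusted p = 0.198). TSC22D3, DDIT4, an inhibitor of mTORC1 signalling (3.00-fold), and YPEL3 rose, and HBP1, a transcriptional repressor, and KLF6, a zinc finger factor, fell 2.00-fold and 2.20-fold. The 10 lower members dropped to 6 without control replicate 1.

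Of 22 YAP/TAZ targets, 1 rose, 16 fell and 5 did not pass (adjusted over the list alone, 2 higher and 17 lower), with a median of -1.42. CCN2, a matricellular growth factor, had 4352 ± 500.4 in the control arrays and 613 ± 58.2 with DCC-2036 (-2.82 ± 0.16), NUAK2, an AMPK-related kinase, fell 8.55-fold, F3, tissue factor, 5.23-fold and CRIM1, a membrane protein that binds BMPs, 4.54-fold. The higher member was IGFBP3, a binding protein of insulin-like growth factors (1.30), with 0 higher and its call lost without control replicate 1 (1.15), DCC-2036 replicate 2 (1.23), control replicate 3 (1.33) or DCC-2036 replicate 3 (1.06). The camera adjusted p was 1.62e-07, and adjusted p = 0.201 with an estimated correlation. Of 28 TGF-beta response genes, 10 rose, 5 fell and 13 did not pass (adjusted over the list alone, 10 higher and 7 lower; camera adjusted p = 0.345). TGFB1, the ligand itself, rose 3.32-fold and SMAD6, an inhibitory SMAD, 2.35-fold, while TGFB2 fell 3.96-fold. SMURF2, TGIF1 and SMURF1 were also lower.

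Of 32 matrix protease and invasion genes, 5 rose, 4 fell and 23 did not pass (adjusted over the list alone, 5 higher and 4 lower); the median was -0.07, while the camera test pointed up (adjusted p = 0.979). MMP15, MMP14, FSCN1, LOX and TIMP1 rose, and PLAU, HPSE, the enzyme that cuts heparan sulphate (7.06-fold), and SERPINB2 were among those that fell. Of 39 integrin, focal adhesion and actin genes, 3 rose, 8 fell and 28 did not pass (adjusted over the list alone, 3 higher and 8 lower; camera adjusted p = 0.483). CAV1, the caveolae coat protein, fell 4.68-fold, LAMA3, a laminin chain, 1.81-fold and MYL9, a myosin light chain, 1.96-fold, and ITGA5, a fibronectin receptor subunit, rose 1.99-fold with ACTN4 and ITGB6. The 3 higher members dropped to 1 without control replicate 1, DCC-2036 replicate 1, DCC-2036 replicate 2 or control replicate 3. The 8 lower members dropped to 3 without control replicate 1 or DCC-2036 replicate 2, 4 without control replicate 2 and 5 without control replicate 3 or DCC-2036 replicate 3.

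Epithelial and mesenchymal markers each moved both ways. Of 29 epithelial markers, 11 rose, 5 fell and 13 did not pass (adjusted over the list alone, 14 higher and 7 lower), with a median of 0.57 (camera adjusted p = 0.169). JUP, plakoglobin of cell junctions, had 1586 ± 155 in the control arrays and 6564 ± 766 with DCC-2036 (2.05 ± 0.16), PKP3, a desmosomal plakophilin, rose 3.88-fold and CLDN3, a tight junction claudin, 3.00-fold. CLDN1, another claudin, fell 7.68-fold, and ELF3, CLDN7, KRT7 and EPCAM were also lower. The 5 lower members dropped to 3 without control replicate 2, DCC-2036 replicate 2 or control replicate 3. Of 26 mesenchymal markers, 4 rose, 5 fell and 17 did not pass (adjusted over the list alone, 4 higher and 5 lower; camera adjusted p = 0.456). COL5A1, a fibrillar collagen chain, rose 5.16-fold and COL6A2, a collagen VI chain, 2.18-fold, with SNAI1 and TNC. SNAI2 and ZEB2, transcription factors of epithelial-mesenchymal transition, fell 2.44-fold and 2.31-fold, with LUM, COL1A2 and VIM. The 5 lower members dropped to 2 without control replicate 1, DCC-2036 replicate 2, control replicate 3 or DCC-2036 replicate 3.

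Of 27 kinases named as DCC-2036 targets or related receptor kinases, 5 rose, 6 fell and 16 did not pass (adjusted over the list alone, 5 higher and 6 lower); the median was 0.08, while the camera test pointed down (adjusted p = 0.970). AXL, a receptor kinase of the TAM family and a YAP/TAZ target, had 12869 ± 354 in the control arrays and 4385 ± 604 with DCC-2036 (-1.56 ± 0.16, limma adjusted p = 0.00169). MET, the receptor of hepatocyte growth factor, fell 2.24-fold (-1.16 ± 0.18) and EPHA2, an ephrin receptor, 2.21-fold. CSF1R rose, as did FGFR1, a fibroblast growth factor receptor (2.68-fold), ABL1 (0.79 ± 0.15), DDR1 and LYN. A second record of ABL1 gave 0.50 and did not pass. SRC had 1466 ± 132 in the control arrays and 1548 ± 168 with DCC-2036 (0.08 ± 0.16, limma adjusted p = 0.748), and TEK (0.35 ± 0.58, limma adjusted p = 0.695), dim in both groups, did not pass either. The 5 higher kinases were 3 without control replicate 1, DCC-2036 replicate 2 or control replicate 3.

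Of 38 hypoxia and glycolysis genes, 13 rose, 1 fell and 24 did not pass (adjusted over the list alone, 14 higher and 1 lower), with a median of 0.29. EGLN3 and EGLN1, prolyl hydroxylases that mark hypoxia-inducible factor for degradation, rose 8.38-fold and 3.64-fold, CA12, a membrane carbonic anhydrase, 4.00-fold and GPI, a glycolytic isomerase, 2.13-fold. HK2, hexokinase 2, fell (-0.57), with 0 lower without control replicate 1, control replicate 2, DCC-2036 replicate 2 or DCC-2036 replicate 3. The camera adjusted p was 0.00325, and adjusted p = 0.178 with an estimated correlation. Of 40 oxidative phosphorylation genes, 12 rose, 0 fell and 28 did not pass (adjusted over the list alone, 12 higher and 0 lower), with a median of 0.33. ATP5F1D, a subunit of ATP synthase, had 415 ± 24.1 in the control arrays and 1332 ± 20.1 with DCC-2036 (1.68 ± 0.13; its second record changed by 0.74), and NDUFS3, NDUFB10 and NDUFA9, subunits of complex I, rose 3.39-fold, 2.85-fold and 1.65-fold. Tested with camera, the list had an adjusted p of 0.000747, and adjusted p = 0.254 with an estimated correlation. The 12 higher members dropped to 7 without control replicate 1, control replicate 2 or DCC-2036 replicate 3 and 6 without DCC-2036 replicate 2.

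Of 42 cytosolic ribosomal proteins, 4 rose, 1 fell and 37 did not pass (adjusted over the list alone, 2 higher and 0 lower; camera adjusted p = 0.569). RPS2 and RPLP2 rose 2.52-fold and 1.67-fold. RPL13 (0.56) lost its call without each of the 6 arrays, with changes of 0.52 without control replicate 1, 0.56 without DCC-2036 replicate 1, DCC-2036 replicate 2 or DCC-2036 replicate 3, 0.60 without control replicate 2 and 0.57 without control replicate 3, and RPS23 (0.64) without control replicate 1 (0.66), DCC-2036 replicate 1 (0.55), control replicate 2 (0.60), DCC-2036 replicate 2 (0.63) or control replicate 3 (0.66). RPL6 fell. The 4 higher members dropped to 2 without these same 5 arrays, and the 1 lower member was 0 without control replicate 1, control replicate 2, DCC-2036 replicate 2, control replicate 3 or DCC-2036 replicate 3.

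Lipid genes moved both ways. Of 26 cholesterol synthesis genes and SREBP2 targets, 3 rose, 5 fell and 18 did not pass (adjusted over the list alone, 4 higher and 5 lower; camera adjusted p = 0.483). INSIG1, a sterol-regulated brake on SREBP processing, had 5370.4 ± 664 in the control arrays and 1686 ± 152 with DCC-2036 (-1.67 ± 0.16), and ACAT2, FDPS and HMGCS1 also fell, while the sterol synthesis enzymes LSS and MVD each rose 2.34-fold, with MVK. Of 17 fatty acid synthesis and desaturation genes, 5 rose, 3 fell and 9 did not pass (adjusted over the list alone, 5 higher and 3 lower); the median was -0.14, while the camera test pointed up (adjusted p = 0.934). ELOVL7, a fatty acid elongase, and FADS1, a desaturase, fell 4.54-fold and 2.76-fold, with ELOVL5. FADS2, another desaturase, rose 2.26-fold, and SCD5, a stearoyl-CoA desaturase, 2.71-fold (second record 0.32, not passing), with ACSL1, ACSS2 and ACACB. The 5 higher members dropped to 3 without control replicate 1 or control replicate 3 and 2 without control replicate 2, DCC-2036 replicate 2 or DCC-2036 replicate 3.

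Of 39 lysosome and autophagy genes, 11 rose, 6 fell and 22 did not pass (adjusted over the list alone, 12 higher and 6 lower; camera adjusted p = 0.370). LAMP1, a lysosomal membrane protein, rose 2.33-fold, TFEB, the master transcription factor of lysosome genes, 2.51-fold and GRN, progranulin, 1.80-fold, while MAP1LC3B, an autophagosome membrane protein, fell 2.38-fold. The 11 higher members dropped to 7 without control replicate 1 or DCC-2036 replicate 3, and the 6 lower members dropped to 3 without control replicate 1. Of 38 endoplasmic reticulum stress genes and ATF4 targets, 9 rose, 3 fell and 26 did not pass (adjusted over the list alone, 9 higher and 4 lower; camera adjusted p = 0.432). HSPA5, the chaperone BiP, had 435 ± 119 in the control arrays and 2113 ± 311 with DCC-2036 (2.31 ± 0.25) and PDIA4, a disulfide isomerase, rose 1.65-fold, while ATF3, a stress-induced transcription factor, PPP1R15A, the phosphatase subunit GADD34, and SESN2 fell, the first by 3.53-fold and the next by 3.91-fold. The 9 higher members dropped to 5 without control replicate 1 or DCC-2036 replicate 3 and 3 without control replicate 2 or DCC-2036 replicate 2.

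Of 31 NRF2 and oxidative stress genes, 7 rose, 2 fell and 22 did not pass (adjusted over the list alone, 7 higher and 2 lower; camera adjusted p = 0.198). HMOX1, haem oxygenase 1, rose 2.65-fold, EPHX1, microsomal epoxide hydrolase, 2.23-fold, and the aldo-keto reductases AKR1C3 and AKR1C2 2.70-fold and 2.55-fold, although near-identical sequences of this family leave the single gene uncertain. TXNRD1 and BLVRB fell, and the 2 lower members dropped to 1 without control replicate 1, control replicate 2, DCC-2036 replicate 2, control replicate 3 or DCC-2036 replicate 3. Of 24 heat shock genes, 3 rose, 6 fell and 15 did not pass (adjusted over the list alone, 3 higher and 7 lower; camera adjusted p = 0.421). HSPB1, a small heat shock protein, HSF1, the heat shock transcription factor, and BAG3 rose 2.47-fold, 2.50-fold and 2.21-fold, and FKBP4, a co-chaperone of HSP90, fell 1.74-fold.

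Markers of other cell types and tissues served as a check on the cultures. Of 20 luminal breast markers, 2 rose, 2 fell and 16 did not pass (adjusted over the list alone, 2 higher and 2 lower; camera adjusted p = 0.483): CA12 and KRT8, a simple epithelial keratin (2.36-fold), rose and NAT1, an arylamine acetyltransferase (2.53-fold), and GATA3, a luminal transcription factor (-0.68), fell. GATA3 lost its call without control replicate 1 (-0.63), control replicate 2 (-0.68), DCC-2036 replicate 2 (-0.60) or DCC-2036 replicate 3 (-0.66), each of which left 1 lower member. Of 26 leukocyte markers, 2 rose, 1 fell and 23 did not pass (adjusted over the list alone, 1 higher and 0 lower; camera adjusted p = 0.110); CSF1R rose, LAPTM5, a lysosomal membrane protein of blood cells (0.92), lost its call without control replicate 1 (0.98), control replicate 2 (0.93), DCC-2036 replicate 2 (0.81), control replicate 3 (0.84) or DCC-2036 replicate 3 (0.77), and ZAP70, a T-cell kinase (-1.53; second record -0.27), without control replicate 1 (-1.58), control replicate 2 (-1.48), DCC-2036 replicate 2 (-1.59) or control replicate 3 (-1.54). The 2 higher leukocyte markers were 1 without control replicate 2 or DCC-2036 replicate 2, and the 1 lower was 0 without control replicate 2, DCC-2036 replicate 2 or control replicate 3.

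Of 17 endothelial markers, 1 rose, 2 fell and 14 did not pass (adjusted over the list alone, 0 higher and 1 lower; camera adjusted p = 0.569). ROBO4, a guidance receptor of vessels (-1.67), lost its call without control replicate 1 (-1.67), and KDR, the VEGF receptor (-1.03), without control replicate 1 (-1.11), DCC-2036 replicate 1 (-0.81), control replicate 2 (-0.89), DCC-2036 replicate 2 (-1.01) or control replicate 3 (-1.10). EGFL7 (0.62), a secreted vascular factor, did without control replicate 1 (0.56), DCC-2036 replicate 1 (0.50), control replicate 2 (0.72), DCC-2036 replicate 2 (0.62) or control replicate 3 (0.58). The 2 lower members dropped to 0 without control replicate 1 and 1 without DCC-2036 replicate 1, control replicate 2, DCC-2036 replicate 2 or control replicate 3, and the 1 higher was 0 without control replicate 1, control replicate 2, DCC-2036 replicate 2 or control replicate 3. Of 24 liver and pancreas genes, 5 rose, 0 fell and 19 did not pass (adjusted over the list alone, 4 higher and 0 lower; camera adjusted p = 0.409). CYP2E1, a cytochrome P450, had 80.5 ± 7.70 in the control arrays and 421 ± 18.6 with DCC-2036 and PRSS1, trypsinogen, 79.6 ± 34.6 in the control arrays and 304 ± 72.4 with DCC-2036. The others were SERPINA1, APOC3 (0.87), whose call was lost without control replicate 1 (0.91) or control replicate 2 (0.79), and APOA1 (0.68), whose call was lost without control replicate 1 (0.60), DCC-2036 replicate 1 (0.62), DCC-2036 replicate 2 (0.63) or control replicate 3 (0.66). The 5 higher members dropped to 2 without control replicate 1 and 3 without DCC-2036 replicate 1, control replicate 2, DCC-2036 replicate 2 or control replicate 3, and the 0 lower were 2 without control replicate 3.

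**Figure D3:**
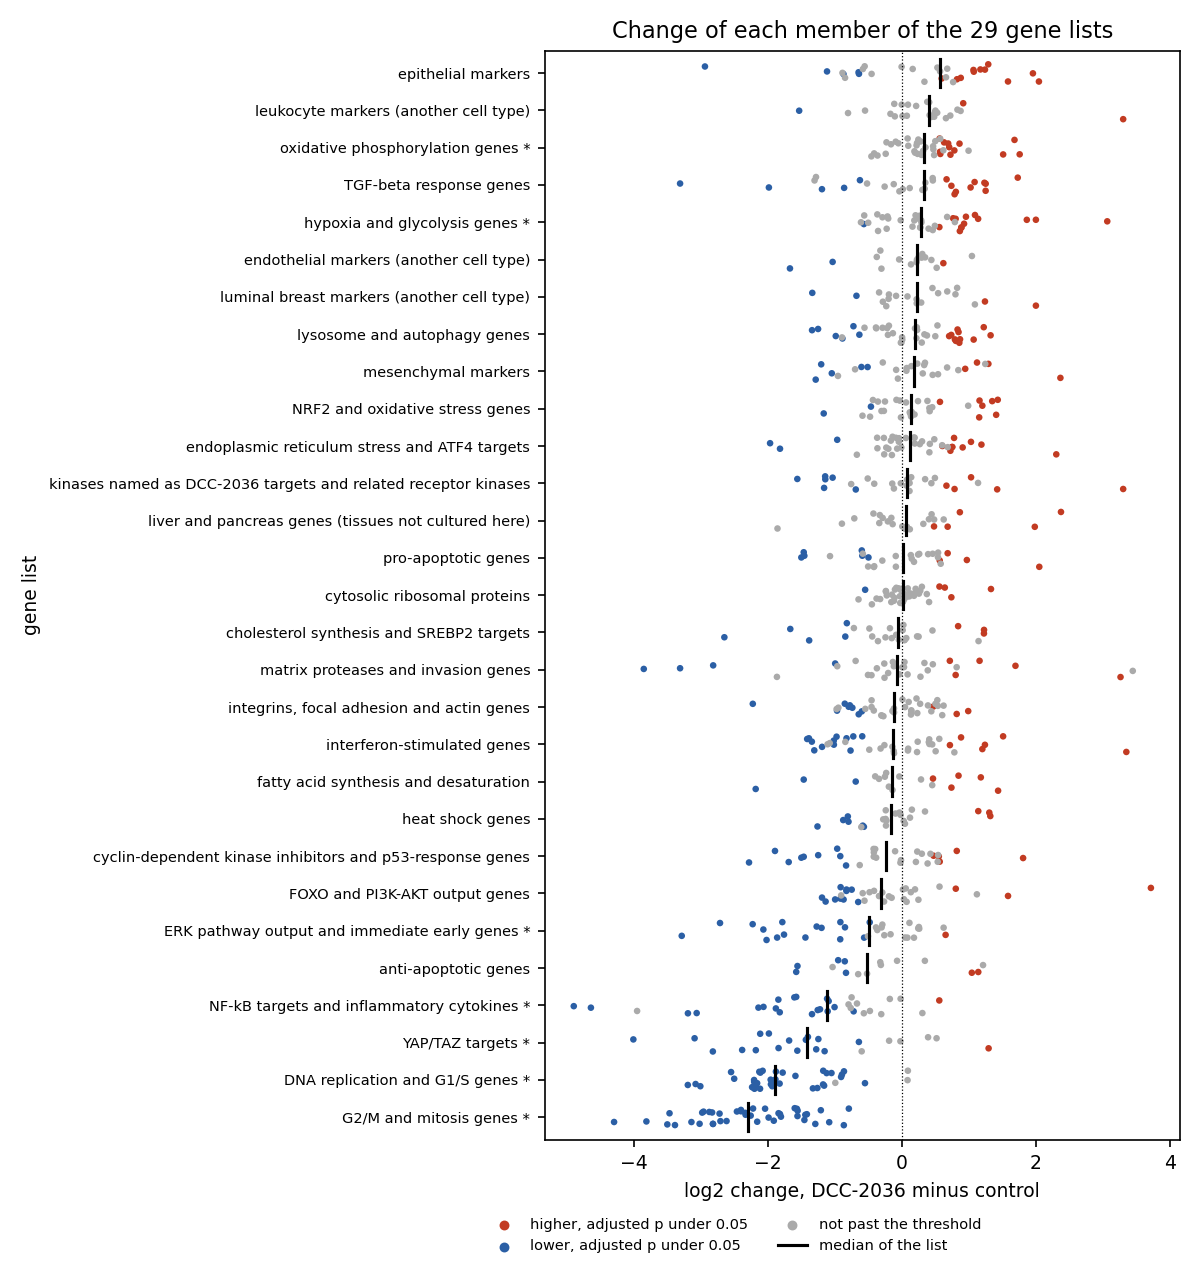
Log2 change (DCC-2036 minus control) of every measured member of the 29 gene lists, with each list's median as a black bar; red and blue points are members higher and lower at an adjusted p under 0.05, and an asterisk marks the 7 lists past the camera threshold with the preset correlation, of which 0 were past it with an estimated correlation. The lowest medians are those of mitosis genes (-2.30) and replication genes (-1.90), and the highest is that of epithelial markers (0.57).

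Across the 29 lists, 7 passed the camera test at an adjusted p under 0.05, 5 lower (replication, mitosis, ERK output, NF-kB and YAP/TAZ) and 2 higher (hypoxia and glycolysis, oxidative phosphorylation). With an estimated correlation in place of the preset 0.01, 0 lists passed. The smallest adjusted p was then 0.178, and 5 lists had an unadjusted p under 0.05. This setting changed more than the correlation. For hypoxia and glycolysis the estimate was -0.0037, below the preset, yet the unadjusted camera p went from 0.000784 to 0.0171. The loss of that call thus did not come from a higher correlation. For the other lists the loss cannot be credited to correlation alone. The fry test, which asks only whether the members of a list move on balance one way, passed 18 lists. Among them were leukocyte markers (fry adjusted p = 0.00285) and liver and pancreas genes (0.0190), which served as a check. Luminal (0.280) and endothelial markers (0.260) did not pass. Lists with members moving both ways also passed, such as the p53-response list (0.000530) and epithelial markers (0.000761). A fry pass therefore does not set a list apart.

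Many of the list members named only to spell out a small count sat near the threshold and did not pass when 1 array was left out. Without control replicate 1, calls were lost by ZMAT3 (0.49), BIRC3 (-1.52), BCL2L1 (-0.86), BCL2 (0.98), DUSP4 (0.62), YPEL3 (0.77), SMURF1 (-0.61), TIMP1 (0.62), ACTN4 (0.47), ITGB6 (0.93), KRT7 (-0.64), TNC (1.20), LUM (-0.90), COL1A2 (-0.60), VIM (-0.50), DDR1 (1.10), LYN (0.61), HK2 (-0.51), RPL6 (-0.46), HMGCS1 (-0.86), ACSS2 (0.67), ACACB (0.47), SESN2 (-0.84), BLVRB (-0.45) and SERPINA1 (0.52). Without control replicate 2, calls were lost by ZMAT3 (0.56), BBC3 (0.49), BIRC3 (-1.62), BCL2L1 (-0.87), BCL2 (0.99), DUSP4 (0.59), SMURF1 (-0.59), SERPINB2 (-0.89), ACTN4 (0.49), ITGB6 (0.80), KRT7 (-0.66), EPCAM (-0.55), TNC (1.15), COL1A2 (-0.62), VIM (-0.57), DDR1 (1.00), HK2 (-0.52), RPL6 (-0.63), HMGCS1 (-0.98), ACSL1 (0.71), ACSS2 (0.69), ACACB (0.51), SESN2 (-0.95), BLVRB (-0.46) and SERPINA1 (0.50). Without control replicate 3, calls were lost by ZMAT3 (0.60), BBC3 (0.53), BIRC3 (-1.59), BCL2L1 (-0.83), SMURF1 (-0.68), SERPINB2 (-0.88), ACTN4 (0.45), ITGB6 (0.73), KRT7 (-0.62), EPCAM (-0.61), LUM (-0.99), COL1A2 (-0.60), VIM (-0.46), DDR1 (0.99), LYN (0.61), RPL6 (-0.56), HMGCS1 (-0.69), ACSL1 (0.83), ACACB (0.41), BLVRB (-0.48) and SERPINA1 (0.42). Without DCC-2036 replicate 1, calls were lost by ZMAT3 (0.53), BBC3 (0.53), BCL2 (1.08), DUSP4 (0.60), SMURF1 (-0.52), ACTN4 (0.53), ITGB6 (0.85), KRT7 (-0.60), EPCAM (-0.62), VIM (-0.57), LYN (0.63), HK2 (-0.55), RPL6 (-0.58), HMGCS1 (-0.96), ACACB (0.44), BLVRB (-0.41) and SERPINA1 (0.45). Without DCC-2036 replicate 2, calls were lost by ZMAT3 (0.51), BBC3 (0.59), BIRC3 (-1.82), DUSP4 (0.67), SERPINB2 (-0.96), ACTN4 (0.45), ITGB6 (0.60), KRT7 (-0.59), EPCAM (-0.76), TNC (1.21), LUM (-1.08), COL1A2 (-0.56), VIM (-0.45), DDR1 (0.97), LYN (0.67), HK2 (-0.60), RPL6 (-0.51), HMGCS1 (-0.92), ACSL1 (0.86), ACSS2 (0.70), ACACB (0.47), BLVRB (-0.47) and SERPINA1 (0.48). Without DCC-2036 replicate 3, calls were lost by BBC3 (0.58), SMURF1 (-0.61), SERPINB2 (-0.90), ACTN4 (0.43), EPCAM (-0.56), LUM (-0.86), COL1A2 (-0.54), VIM (-0.52), DDR1 (0.86), HK2 (-0.55), RPL6 (-0.55), HMGCS1 (-0.66), ACSL1 (0.79), ACSS2 (0.70), ACACB (0.48), BLVRB (-0.51) and SERPINA1 (0.51).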

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

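The histone families and genes, the tests of S phase and of signal shared between H2B copies, and the test of other beta-catenin targets given under the other observations, were chosen after the results were seen. The remaining tests in this part were chosen before, except that rescaling was applied to the H2B genes only after that group had been picked.

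Records without a gene name carried signal that the gene comparison did not use. Of the 26167 unnamed records, 3253 were higher and 3208 lower with DCC-2036 in the limma test of all 45033 records. That was 24.7% of them, beside 26.0% of all records in the same test. In the separate test of named genes, each by its brightest record, 29.1% changed. What these records measure is not given in the sources used here.

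The replication and mitosis genes fell together: 78 of 81 members of both lists were lower, with a median log2 change of -2.04. The median was -2.01 under the rescaling that brought it nearest to 0. The arrays already had close medians, and rescaling moved the median change of all genes only from 0.02 to 0.01. Rescaling could thus hardly have removed the fall, and any error of scaling made within RMA was not tested. Signal level and gene length did not give such a fall, since the lowest of 10000 random lists matched on both had a median of -0.37. No single array carried it, since at least 73 members were past the threshold and lower whichever array was left out. These tests bear on the lower mRNA only; whether fewer cells divided was not tested.

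The H2B histone genes rose: of 18 measured, 16 were higher and 0 lower, with a median log2 change of 1.04. The other histone families did not all follow. Of 16 H2A genes 6 were higher and 0 lower (median 0.46), with 2 higher without control replicate 1, DCC-2036 replicate 2 or DCC-2036 replicate 3, and of 5 H1 genes 2 were higher, H1-2 and H1-3 (median 0.29), and 1 when any array but DCC-2036 replicate 1 was left out, as H1-2 (0.63) then changed by between 0.50 and 0.70. Of 12 H3 genes 0 were higher and 3 lower, H3C3, H3C7 and H3C11 (median -0.24), with 1 lower without control replicate 1 or DCC-2036 replicate 3, 0 lower without control replicate 2 or control replicate 3, and 1 higher without control replicate 2. Of 14 H4 genes 1 was higher, H4C13 (1.09), and 3 lower, H4C2 (-1.31), H4C3 (-1.88) and H4C12 (-1.42), with a median of -0.41; 5 were lower without control replicate 1 and 2 higher without DCC-2036 replicate 1. More cells in S phase, taken here to raise histone and replication genes together, would need the replication list at or above 0. Its median was -1.90, which was known before this test was chosen. The cDNA was primed with oligo dT, which favours transcripts with a poly(A) tail. Whether the histone signals stand for the histone mRNA of S phase was not tested. After rescaling the arrays, the lower of both H2B medians was 1.03. Rescaling could hardly have removed this rise, for the reason given above for the replication and mitosis genes. Signal shared between near-identical copies stays open. Only 0.59% of 10000 random lists matched on mean signal had changes that spread as little, but separate genes that rise together would give this too, so the spread does not decide. Whether 1 H2B transcript or several rose was not tested.

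Other splits of the 6 arrays into 3 and 3 are too few, 10 in all, to give a share under 0.05. For the genes higher, the genes lower and both counts with at least a 2-fold change, 1 split, the real one, gave the count reported (2257, 2746, 1056 and 1460), and the highest count in any other split was 0 in limma. For lists past the camera threshold, 2 splits gave 7 lists, the real one and the split of control replicates 1 and 2 with DCC-2036 replicate 3 against the rest. The other splits gave between 2 and 5. Every split but the real one has arrays of both groups on each side. The difference between the groups then adds to the spread within a side, so gene counts near 0 could be foreseen and lend no support. The list counts of these mixed splits do not show what chance gives either.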

How the results depend on the processing

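Among the alternatives, those applied to single records, to counts of list members, to genes named beyond the rule and to gene groups added later were added after the data were seen, and the rest were chosen before. Genes past the threshold in both the reported test and an alternative changed the same way under each alternative, except 2 genes with the mean of a gene's records and 12 with its second record. Both scalings moved the median log2 change of all genes by little (0.02 as deposited, 0.01 with quantile normalization, 0.01 with median centring). Genes higher ranged from 1422 to 1885 and genes lower from 1725 to 2307 when 1 array was left out, against 2257 and 2746 with all 6, and records higher from 3246 to 4575 and lower from 3664 to 5083, against 5616 and 6091. The lowest gene counts were those without control replicate 1, and 1461 genes were higher without DCC-2036 replicate 2. Fewer arrays leave fewer degrees of freedom; beyond that, the cause was not tested. Without the dimmer records (mean below the median), 703 genes were at least 2-fold higher, against 1056, and 995 at least 2-fold lower, against 1460. Only 9023 genes were tested there, yet 2296 were higher by any amount, against 2257. The smaller number of genes tested therefore does not by itself account for the drop in 2-fold rises. At an adjusted p of 0.01, 884 genes were higher and 1289 lower. A plain t-test with an unadjusted p under 0.05 and a 2-fold change gave 1062 and 1461, and after Benjamini-Hochberg adjustment without a fold minimum 1814 and 2263.

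With the replicate block, 1380 genes were higher and 1797 lower, and 3163 records higher and 3726 lower; log2 changes stayed equal and the residual degrees of freedom went from 4 to 2. Arrays with the same replicate number did not deviate together: their deviations correlated at -0.08, 0.04 and -0.09, and the highest correlation with another number was 0.04, 0.06 and 0.15. Whether they came from the same experiment cannot be told from this. The block changed the call of none of the 29 lists at the camera threshold, where 7 passed, but 12 of the 132 genes named by the rule lost their calls: CABP5, PDIA4, BCL2L2, RPL13, RPS23, GATA3, LAPTM5, KDR, EGFL7, APOC3, APOA1 and CDKN1A, with adjusted p between 0.0503 (PDIA4) and 0.119 (CDKN1A). Of the 85 genes named beyond the rule, 34 lost theirs. Calls of genes named by the rule were also lost with the plain t-test (7), the second record (6) and the mean of records (3). The trend and robust settings lost 1, and leaving out 1 array lost between 5 and 12. The other settings lost 0, but of the 132 genes only 127 were tested without the dimmest 25% of records and 103 without the dimmer ones. Genes named beyond the rule lost calls with the plain t-test (15), the trend and robust settings (6), and median centring and 16 added before the log (1 each). Quantile normalization, the mean of records, the second record and array weights lost 3 each. With its second record BCL2 also lost its call, with a change in the other direction. Between 20 and 33 lost theirs when 1 array was left out. Of the 85 genes, 80 were tested without the dimmest 25% of records and 72 without the dimmer ones. Among genes named beyond the rule, calls were gained without the dimmest 25% of records (2), without the dimmer records (1), with array weights (1) and without DCC-2036 replicate 1 (2), all by CXCL8 or SP5.

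Each of the 7 lists past the camera threshold was past it in 17 of 18 alternatives, all but the estimated correlation, which gave adjusted p values of 0.178 (replication, mitosis, hypoxia and glycolysis), 0.201 (ERK output, YAP/TAZ), 0.254 (oxidative phosphorylation) and 0.389 (NF-kB). Epithelial markers passed without the dimmer records (0.0211) and among genes above the median mean (0.00487), with 0.169 as reported; leukocyte markers passed in the same settings (0.0378 and 0.0378), with the mean of a gene's records (0.0482) and with the second record (0.0303), with 0.110 as reported. The cause was not tested. Over the alternatives, adjusted p ranged up to 0.338 for epithelial and 0.301 for leukocyte markers.

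Without background or detection values, changes of dim genes depend on the number added before the log: with 16, CENPI changed by -3.52, BLM by -3.31, SPC25 by -3.20, MCM10 by -2.42 and POLQ by -2.76. In 19 of the 132 named genes a group mean lay in the dimmest 25% of records, BTG2, CDKN1C, EREG, ELOVL7, ZAP70 and APOC3 among them. BCL2, 1.04 as reported, was -0.71 and did not pass with its second record; the cause was not tested. The plain t-test gives no list test, and the floor planned for log2 values was not run because the values were linear.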

Other observations

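The tests and gene groups in this part were all chosen after the data were seen, and their genes were named after their values were seen.

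Genes of homologous recombination and the Fanconi pathway, which repair broken and cross-linked DNA, were lower: of 29 measured, 0 rose and 22 fell, with a median log2 change of -1.77. BRCA1 (-2.79 ± 0.16, standard error, n = 3 per group), BRCA2 (-3.12), POLQ, the polymerase of end joining (-3.37, with a dim treated mean, and -2.76 with 16 added before the log), and EXO1, a nuclease (-3.18), fell too. Of 11 ligands of T-cell co-receptors, 2 rose and 5 fell. CD274, the checkpoint ligand PD-L1, had an intensity of 1061 ± 136 (SD) in the control arrays and 121 ± 6.70 with DCC-2036 (-3.11 ± 0.16, limma adjusted p = 0.000604), and PDCD1LG2 (-1.14), ICOSLG (-1.87), TNFSF9 (-1.43) and PVR (-1.05) also fell. CD276, the ligand B7-H3, rose (2.03 ± 0.15), with VTCN1 (0.93), whose call was lost, leaving 1 higher, without control replicate 1 (0.80), control replicate 2 (1.01), DCC-2036 replicate 2 (0.98), control replicate 3 (0.98) or DCC-2036 replicate 3 (0.74).

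Of 6 targets of the aryl hydrocarbon receptor, 3 rose and 0 fell: CYP1A1 (2.17 ± 0.20), ALDH3A1 (1.87 ± 0.26) and CYP1B1, with 2745 ± 572 in the control arrays and 7745 ± 1538 with DCC-2036; TIPARP (-0.27) did not pass. Of 17 clock and PAR bZIP genes, 4 rose (DBP, TEF at 0.98, CRY2 at 1.29 and BHLHE40 at 0.89) and 4 fell (CRY1 at -1.23, NR1D2 at -1.28, BMAL1 at -0.85 and NFIL3 at -0.58). The 4 higher were 2 without DCC-2036 replicate 2 or control replicate 3. TEF lost its call without control replicate 1 (0.97), DCC-2036 replicate 2 (0.90) or control replicate 3 (0.94), BHLHE40 without control replicate 2 (0.89), DCC-2036 replicate 2 (0.77), control replicate 3 (0.82) or DCC-2036 replicate 3 (0.83), and NFIL3 without any 1 of the 6: control replicate 1 (-0.52), DCC-2036 replicate 1 (-0.65), control replicate 2 (-0.58), DCC-2036 replicate 2 (-0.48), control replicate 3 (-0.65) and DCC-2036 replicate 3 (-0.62). In genes with records past the threshold in both directions, the gene-level value depends on the record: 2 records of CDCP1, a membrane protein, changed by 1.68 and -0.65.

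DKK1, an inhibitor of Wnt signalling, fell by 5.10 on the log2 scale and AXIN2, a target of beta-catenin, rose by 2.63. Both changes could point to a general rise of beta-catenin targets. DKK1 is also counted as a target of beta-catenin, and as such its fall goes against a general rise. Of 10 other targets measured, 0 were past the threshold and higher in limma and 1, TCF7 (-1.25), was lower. The change was above 0 in 8 of them, most of all in SP5 (1.15 ± 0.37, limma adjusted p = 0.0610), which passed without DCC-2036 replicate 1 (1.55), without the dimmest 25% of records (adjusted p = 0.0380) and with array weights (1.22, adjusted p = 0.0381), each time making the count 1, and their median was 0.28, less than their median standard error of 0.38. A general rise therefore stays open.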
